A study of Drosophila melanogaster with 3 samples.

How the data were processed

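Chromatin of whole prepupae, pooled over both sexes, was precipitated with an antibody against GFP from flies expressing achi fused to eGFP, per the sample description. Another label gives achi as the antibody's target; the anti-GFP description was followed. The labels number 3 biological replicates, which form the single group; they do not say whether the replicates share a day or a batch. The analysis started from the authors' peak lists, and no reads were used.

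Per the deposited file descriptions, each replicate list and the pooled list were made from alignments and a control, and the control was the same for all of them. The optimal list was made by the authors from the replicate and pooled lists with a threshold on the irreproducible discovery rate. The aligner, the peak caller and their versions are not given in the sources used here. Each list gives a signal value per region, the authors' own score of enrichment, and the -log10 of a q-value, also the authors', which saturates: 7035 of the 8998 optimal peaks share its maximum. Whether the deposited signal was scaled to depth is not stated, so signal was used only to rank regions within a list. The optimal list holds 46 intervals listed again with another summit, and each summit was kept. Because all lists share a control, a fault of that control would appear in all 3 replicates, and agreement between replicates does not exclude it. No precipitation from flies without the tag was analysed here.

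The coordinates are dm6, the Release 6 assembly, and genes and TSSs were taken from Ensembl release 115. The lists in dm3 coordinates were used only where no annotation was needed. Summits were put into the first class that applied of promoter (within 500 bp of a protein-coding TSS), 5' UTR, 3' UTR, coding exon, intron, other gene and intergenic. A gene was bound when a summit lay within 500 bp of any of its TSSs, so a summit in a shared or divergent promoter counts for each gene there, and genes with more TSSs have more chances. To compare lists of equal length, each replicate's 8998 strongest regions were taken as its top list. Percent rank is the rank within a replicate's own list of 30000 regions, 100 being the strongest; a peak took the value of the strongest region that overlapped it by at least 1 bp.

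Positions were tested against 1000 circular shifts of the summits along each arm with a fixed seed. Sequence words were searched on both strands within 100 bp of the summit and in windows of the same width 1000 bp to each side. The flank share is the mean of both sides, and the exact McNemar test compared the summit with the right-hand window. Hexamers found in at least 1% of flank windows were ranked by the ratio of summit to flank share. Gene lists were tested with Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment, and again with 10000 random lists matched on the number of TSSs and on gene length in 5 classes. Of 650 gene symbols written out in the lists, 28 matched no gene name in the annotation and were left out. Differences of median rank were tested with 100000 permutations. Intervals are 95%, Wilson for shares and exact for odds ratios, and cover counting error only. Genes and peaks are not independent replicates, so tests over them describe these lists, and the values of the 3 replicates stand beside them.

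Named genes followed a rule: achi and vis, the nearest genes of the 15 strongest optimal peaks found in the top lists of all 3 replicates, and the bound members with the highest mean percent rank, 4 from each called list and up to 2 from each other list. This rule, the gene lists, the fixed words, the tests and most alternatives were set before the data were examined. Alternatives left out each replicate in turn (optimal peaks with a summit in the top lists of both others), kept the stronger 50% of peaks, and changed the build, overlap, list length, promoter window, motif window, flank, gene assignment or measure. In the tests of position, sequence and gene lists, leaving out a replicate kept the pooled summits and signal, made from all 3 replicates. Such a subset only holds fewer peaks, so a call can end there without a weaker effect. Overlaps other than the summit used 100 shifts.

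The functions were tested on simulated data. After TGACAG was written into a known share of 5000 random windows, 16.7% of windows were found to hold it against 16.6% expected. On 50 sets of circularly shifted summits, the test over 13945 genes called 0.32 lists on average and 2 at most. Circular shifts put 11.4% of summits at promoters on average, against 32.5% of the optimal summits. The simulation therefore does not give the rate of false calls for peaks gathered at promoters. A planted list of 30 genes was called in 33% of 100 simulations at an odds ratio of 3 and in 84% at an odds ratio of 5, so moderate effects in short lists can be missed. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Several genes that the naming rule selects are not reported here.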

Results

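Achintya (achi) is a TGIF-class homeodomain protein of Drosophila melanogaster, encoded next to its near-identical copy vismay (vis). Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done with an antibody against GFP on whole prepupae of pooled sex, the stage at which larval tissues are dismantled and adult ones are built. The flies carried achi with GFP fused to its C-terminus. There was 1 group with 3 biological replicates, so the comparisons are between replicates, between genomic regions and between gene groups. Each replicate list and the pooled list held 30000 regions, and the authors' optimal list held 8998 peaks in dm6 coordinates. The read depth behind the lists is unknown. At a q-value of at most 0.01 the replicates held 9744, 10649 and 10283 regions (mean 10225 ± 455, SD, n = 3). All optimal peaks lay on 6 chromosome arms: 2080 on 3L, 2049 on 3R, 1685 on X, 1652 on 2L, 1515 on 2R and 17 on chromosome 4.

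The first comparison was between the replicates. The peaks at the ribosomal protein gene RpL23A, at CG5885, at the ribosomal protein gene RpL7 and at the proteasome subunit gene Rpn9 led the pooled ranking, and each had a mean percent rank of at least 99.99 in the replicates' own lists. Across all optimal peaks, 86.8%, 87.7% and 88.7% had their summit in a region of the equally long top list of replicates 1, 2 and 3 (mean 87.7% ± 0.962, SD, n = 3). In all 3 lists together 6484 peaks (72.1%, Wilson 95% interval 71.1% to 73.0%) were recovered, and 40 peaks (0.445%) were in none. Across peaks, Spearman's rho of the replicates' signal was 0.857 for replicates 1 and 2, 0.840 for 1 and 3 and 0.864 for 2 and 3. Peaks are not independent replicates, and the optimal list was itself made from these lists, so no p-value is given for recovery or for rho. The share in all 3 lists was 38.1% with replicate lists of 4499 regions in place of 8998, where the shorter lists themselves set a ceiling.

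Peaks were concentrated at promoters and nearly absent from coding exons. Of the 8998 summits, 2928 (32.5%, Wilson 95% interval 31.6% to 33.5%) lay within 500 bp of a transcription start site (TSS) of a protein-coding gene, a window covering 11.5% of the arms. The replicates' top lists held 34.3% ± 2.76 (SD, n = 3) at promoters, against 13.5% of the lowest 10000 pooled regions. Coding exons cover 13.3% of the arms and held 15 summits (0.167%), while 2.27% of the lowest pooled regions lay there. Introns held 43.4% of summits against 39.3% of the sequence, intergenic DNA 20.1% against 27.8%, 3' UTRs 0.811% against 5.16% and 5' UTRs 0.489% against 0.792%. Of the lowest pooled regions, 47.15% lay in introns, 30.9% in intergenic DNA, 2.14% in 3' UTRs and 0.99% in 5' UTRs. The intron share was thus above that of the sequence but below that of the low-ranked regions. Each of these 6 classes differed from 1000 circular shifts (two-sided permutation p = 0.004 for 5' UTRs and 0.002, the smallest possible, for the others). Other genes held 2.48% against 2.15% (permutation p = 0.208). The promoter share was 20.9% with a window of 200 bp.

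The X chromosome carried a slightly higher share of bound genes than the large autosomes, but not among the stronger peaks. A gene was called bound when an optimal summit lay within 500 bp of a TSS, which held for 3234 of 13945 protein-coding genes (23.2%). The replicates' top lists gave 3714, 3332 and 3157 bound genes (24.4% ± 2.04, SD, n = 3). On the X, 579 of 2196 genes (26.4%) were bound, against 2646 of 11669 (22.7%) on 2L, 2R, 3L and 3R, and on chromosome 4 the count was 9 of 80. The odds ratio of X against autosomes was 1.22 (95% interval 1.098 to 1.36, Fisher's exact test, two-sided p = 0.000201). The call ended with a 200 bp window (odds ratio 1.02, exact p = 0.749) and the direction turned among the stronger 50% of peaks (0.971, exact p = 0.673). Pooled males and females carry fewer copies of the X than of the autosomes, and no correction for this was made here.

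The strongest peaks sat at promoters and held TGACAG, the textbook core sequence of TGIF-class homeodomains. All 15 leading peaks lay at promoters and 14 of them had TGACAG within 100 bp of the summit. Those 14 belonged to genes of ribosomal proteins (RpL23A, RpL7, RpL26, RpS16, RpS13 and RpL14), to Rpn9, to the translocon subunit gene Sec61gamma, to the elongation factor gene eEF1alpha1, to the respiratory genes ND-51 (complex I) and ATPsynE (ATP synthase), to the kinase gene Pkc98E, to CG5885 and to CG6878. The strongest peak of all, at RpL23A (FBgn0026372) on 3L (1668405 to 1669074, dm6, promoter), had its summit at 1668756, 102 bp from the TSS. Its TGACAG lay 61 bp from the summit, within GGAAGCCCGTTTTGACAGGAGGGTGGCCAG (3L 1668680 to 1668709, plus strand). The word lay at 23 of the first 25 peaks, at 50 of the first 100 and at 73 of the first 250. Among the 250 strongest peaks, 178 (71.2%) were at promoters and 38.2% of those held TGACAG (95% interval 31.4% to 45.5%), against 5.90% of their flanks. Below these the share did not fall evenly: promoter peaks of ranks 2001 to 3000 held it in 6.65% of cases, as did their flanks, those of ranks 3001 to 4500 in 12.3% against 4.70% of flanks, and those of ranks 6001 to 8998 in 7.31% against 6.11%.

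**Figure D1:**
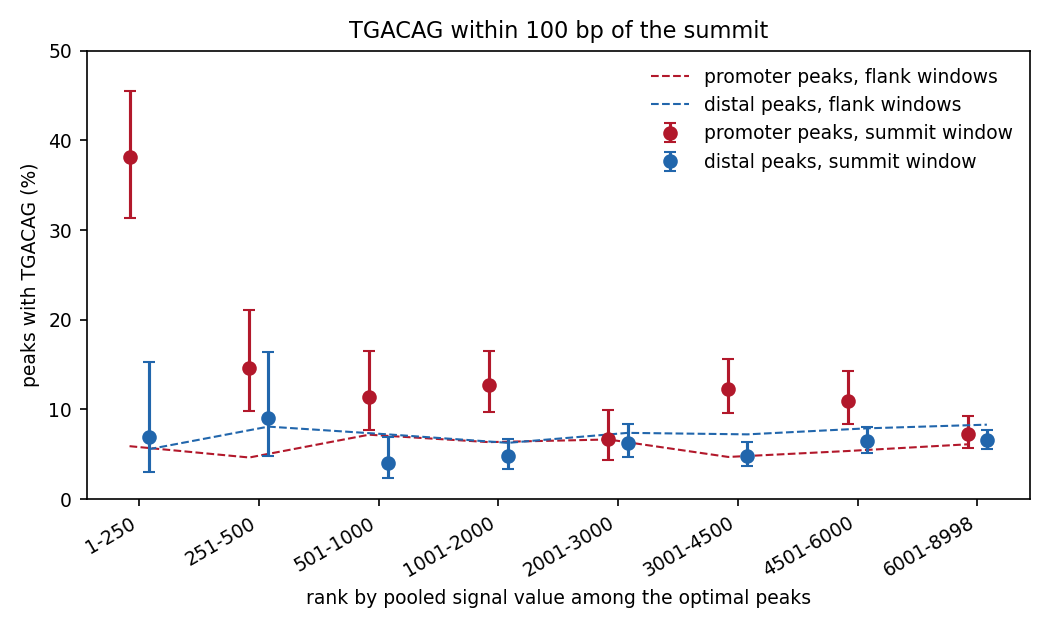
Percent of optimal peaks (y axis) with TGACAG within 100 bp of the summit by rank of pooled signal (x axis), for promoter peaks (red) and distal peaks (blue); bars are Wilson 95% intervals and dashed lines the flank windows 1000 bp away. Promoter peaks of ranks 1 to 250 stand at 38.2% and those of ranks 251 to 500 at 14.6%, while distal peaks of ranks 1 to 250 stand at 6.94%.

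Promoter and distal peaks differed in sequence. TGACAG lay within 100 bp of the summit in 344 of 2928 promoter peaks (11.7% against 5.86% in the flanks, ratio 2.01, exact McNemar test, two-sided p = 3.11e-16). In 6070 distal peaks, more than 500 bp from any protein-coding TSS, it was found in 361 (5.95% against 7.64%, ratio 0.779, exact p = 0.000205), but against low-ranked distal regions of the same GC content, a comparison chosen after seeing the data, the ratio was 0.912 (95% bootstrap interval 0.793 to 1.05). The replicates' top lists gave 11.5% ± 0.341 at promoters and 5.74% ± 0.361 at distal sites (SD, n = 3). The odds ratio of distal against promoter peaks was 0.475 (95% interval 0.406 to 0.556, Fisher's exact test, two-sided p = 1.36e-20). Over all peaks the share was 7.84% against 7.06% (ratio 1.11, exact McNemar p = 0.0483, replicates 7.72% ± 0.306, SD, n = 3). This call ended without replicate 1 (ratio 1.13, exact p = 0.0681), with TTGACAG (1.15, exact p = 0.259) and with a 200 bp window (1.09, exact p = 0.0877). Of these settings, only the 200 bp window gave a lower ratio.

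**Figure D2:**
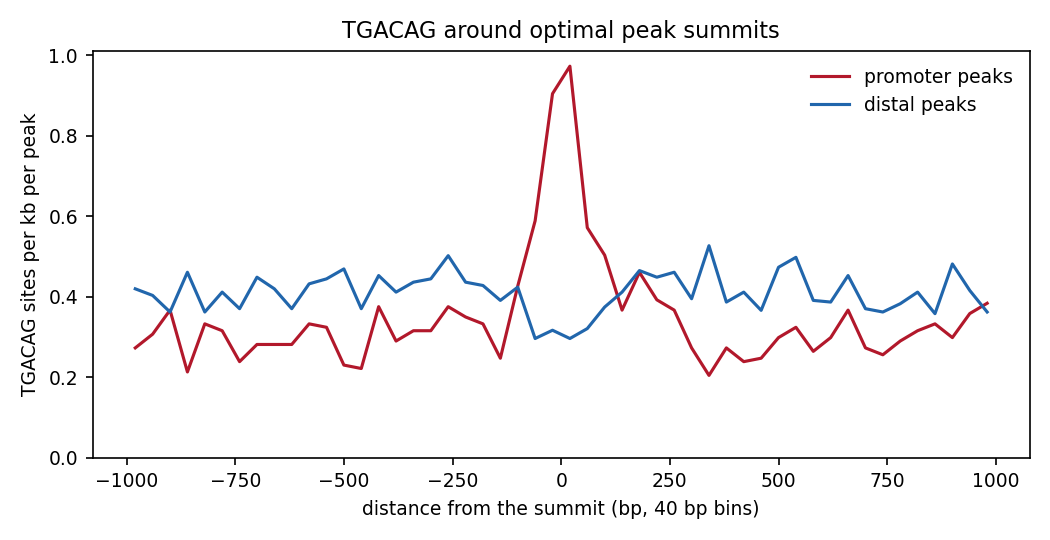
TGACAG sites per kb per peak (y axis) in 40 bp bins by distance from the summit in bp (x axis) for promoter peaks (red) and distal peaks (blue). Promoter peaks rise to 0.973 sites per kb just beside the summit, and distal peaks lie at 0.297 there.

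Among all hexamers, AGTGTA (ratio of summit to flank 2.34), ACACTG (2.26), ATATTA (2.06) and ACAGTG (2.04) led, and TGACAG ranked 541 of 2079. In promoter peaks it ranked 8, after CGATAG (2.88) among others, and after TATCGA and ATCGAT, both parts of the DNA replication-related element. In distal peaks it ranked 1199 of 2078, and AGTGTA (2.59), ACACTG (2.31) and GTGCAC (2.25) led. The replicates' top lists ranked it 403, 572 and 640 (mean 538 ± 122, SD, n = 3).

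Of 9 other fixed sequences, 3 were enriched at summits and 4 depleted after Benjamini-Hochberg adjustment of exact McNemar tests. TATCGATA, the DNA replication-related element, stood out most by ratio, with 2.30% of summits against 0.461% of flanks (ratio 4.99, adjusted exact p = 2.89e-26). TATAAA was found at 37.2% of summits (ratio 1.65, adjusted exact p = 5.41e-103), and the homeodomain site TAATTA at 17.2% (ratio 1.32, adjusted exact p = 1.01e-10). The Zelda site CAGGTAG (ratio 0.759, adjusted exact p = 0.031), the E-box CACGTG (0.743, 0.0145), the nuclear receptor site AGGTCA (0.758, 0.00119) and the repeat CACACA (0.844, 4.95e-06) were less frequent at summits. The GAGA factor site GAGAG was at 22.5% against 22.7% (adjusted exact p = 0.304), and the palindrome TGACANNTGTCA occurred at 5 summits (adjusted exact p = 0.0703). GAGAG passed as depleted without replicate 1 (ratio 0.940, adjusted exact p = 0.00536) and among the stronger 50% of peaks (0.930, 0.0202). These ratios were not adjusted for base composition, and the call of CAGGTAG ended without replicate 3 (adjusted exact p = 0.0703) and among the stronger 50% of peaks (adjusted exact p = 0.137).

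Promoter peaks with TGACAG were also stronger than those without it. Their median percent rank of pooled signal was 71.0 against 56.5, a difference of 14.5 (permutation p = 2e-05, two-sided, the smallest that 100000 resamples can give). For distal peaks the difference was -5.33 (permutation p = 0.0345), and over all peaks 5.96 (permutation p = 0.00208). In the replicates' own 30000-region lists the difference at promoters was 4.66, 4.67 and 4.12 (mean 4.48 ± 0.315, SD, n = 3), higher in 3 of 3. The difference over all peaks was 10.2 with a 50 bp window (permutation p = 4e-05). It was 2.62 with a 200 bp window, where the call ended (permutation p = 0.0765), and 0 with the saturated -log10 q column.

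Of 38 gene lists, 12 were called at an adjusted p under 0.05 (Fisher's exact test, Benjamini-Hochberg), 7 with more and 5 with fewer bound genes than the rest. Ribosomal protein genes stood highest in number, with 67 of 92 bound (72.8%; replicates 71.0% ± 9.86, SD, n = 3; odds ratio 9.04, 95% interval 5.62 to 14.97, adjusted exact p = 2.53e-22). Respiratory chain genes had 31 of 85 bound (odds ratio 1.91, adjusted exact p = 0.0269), led by ND-51, ATPsynE, COX6B and ND-B18. In the Hippo growth pathway 9 of 12 genes were bound (odds ratio 9.96, 95% interval 2.48 to 57.2, adjusted exact p = 0.00114), among them sav, Mer, ft and the transcriptional coactivator yki. Genes of the actin cytoskeleton and adhesion had 20 of 33 (odds ratio 5.12, adjusted exact p = 4.24e-05). The septin gene pnut and Act5C led them by mean percent rank. Percent rank takes the strongest overlapping region, and the Act5C summit itself ranked only 1768 in the optimal list, against 335 for pnut. Cell cycle genes had 17 of 29 (odds ratio 4.71, adjusted exact p = 0.000329), including Dp, CycE, dup and Mcm2. Against 10000 random lists matched on gene length and number of TSSs, these 5 lists were also called (adjusted permutation p between 0.0019 and 0.047). Promoter activity was not matched, here or for the lists below. The calls therefore cannot tell a preference of the tagged protein from capture of active promoters. The respiratory call ended when each summit went only to the nearest gene (adjusted exact p = 0.404), with a 1000 bp window (0.0873) and with summits in the gene body (0.103), and the Hippo call without replicates 1 or 3 (odds ratios 4.25 and 4.04, adjusted exact p = 0.0586 and 0.0677) and with a 200 bp window (2.69, 0.265). The odds ratio of the actin and adhesion list was 3.14 without replicate 1, 3.09 with a 200 bp window and 13.9 with summits in the gene body, called in each.

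The Polycomb and trithorax list had 13 of 28 genes bound (odds ratio 2.88, adjusted exact p = 0.0269), led by ph-p, brm, E(z) and Trl. The ecdysone response list, of genes that respond to or carry this steroid signal at metamorphosis, had 13 of 30 (odds ratio 2.54, 95% interval 1.13 to 5.56, adjusted exact p = 0.048). Its bound genes were led by Hnf4, E23, Eip75B and Hr78, and also included EcR, usp, br, Eip74EF and Eip93F. Neither was called against matched lists (adjusted permutation p = 0.337 and 1), where 12.3 bound genes were expected for the ecdysone list. The Polycomb call also ended when any replicate was left out (adjusted exact p from 0.127 to 0.217) and among the stronger 50% of peaks (0.144), and the ecdysone call without replicate 2 (0.107) and with a 200 bp window (0.297), while its odds ratio was 3.08 with a 1000 bp window and 8.12 with summits in the gene body (adjusted exact p = 0.0127 and 6.19e-07).

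Of the 5 lists called lower, those of cuticle proteins and chemoreceptors were also called against matched lists. None of 118 cuticle protein genes (odds ratio 0, upper 95% bound 0.104, adjusted exact p = 7.7e-13) and 1 of 119 olfactory and gustatory receptor genes, Gr77a (adjusted exact p = 1.48e-11), was bound (adjusted permutation p = 0.0019 against matched lists for both). Of the seminal fluid genes 1 of 47 was bound, Sfp26Ad (adjusted exact p = 0.000572), of salivary glue genes 0 of 20 (adjusted exact p = 0.0272), and of ovary and chorion genes 0 of 19 (adjusted exact p = 0.0402). The last 3 calls ended against matched lists (adjusted permutation p = 0.176, 0.436 and 0.176), and those of glue and chorion also when any replicate was left out (adjusted exact p from 0.0677 to 0.113).

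**Figure D3:**
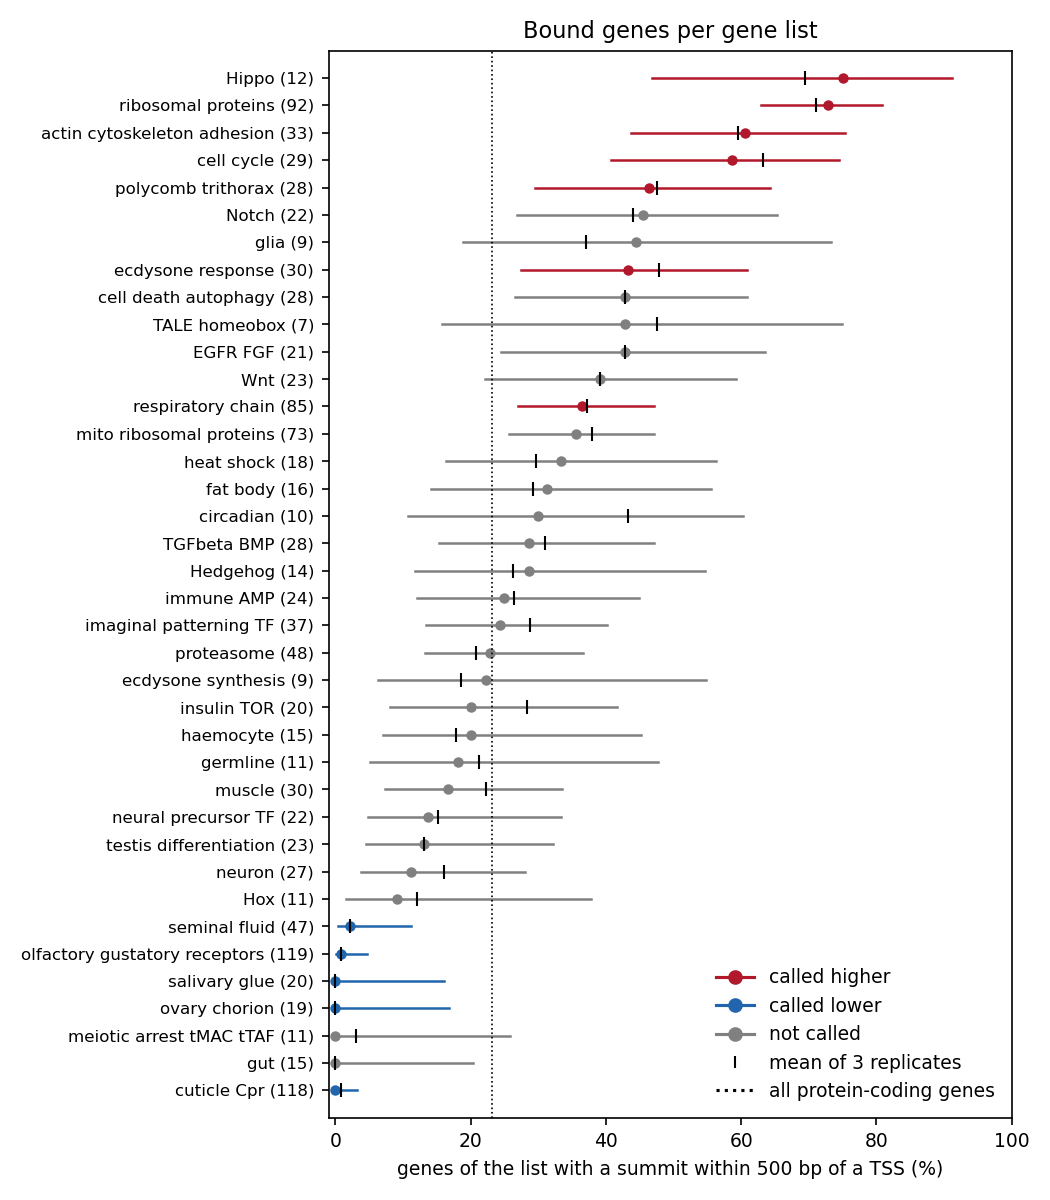
Percent of genes in each list (rows, number of genes in brackets) with a summit within 500 bp of a TSS (x axis), with Wilson 95% intervals; black ticks are the mean of the 3 replicates' top lists and the dotted line all protein-coding genes (23.2%). Ribosomal protein genes stand at 72.8% and cuticle genes at 0%.

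The other 26 lists were not called. Those closest to the threshold were mitochondrial ribosomal proteins, with 26 of 73 bound (adjusted exact p = 0.0503), called without replicate 1 (0.0206) and in the stronger 50% of peaks (0.0497) and led by mRpS23 and mRpL41, Notch signalling with 10 of 22 (0.0561), led by numb and E(spl)mdelta-HLH, and cell death and autophagy with 12 of 28 (0.0565), led by hid and Atg2. Against matched lists, mitochondrial ribosomal proteins (adjusted permutation p = 0.0019) and Notch (0.047) were higher, and neuron genes (3 of 27, 0.0104) and muscle genes (5 of 30, 0.0338) lower. By nearest gene, a setting chosen after seeing the data, mitochondrial ribosomal proteins turned direction (odds ratio 0.626, adjusted exact p = 0.404) while Notch (adjusted exact p = 0.0394) and EGFR and FGF genes (0.0305) were called. EGFR and FGF genes had 9 of 21 bound (adjusted exact p = 0.0894) and were called with a 1000 bp window (adjusted exact p = 0.000842). With summits in the gene body 5 further lists were called, EGFR and FGF (adjusted exact p = 4.88e-05), Wnt (0.000238), imaginal patterning (0.00142), cell death and autophagy (0.0477) and TGF-beta and BMP (0.0477). In other signalling lists, the counts were 9 of 23 Wnt genes, 8 of 28 TGF-beta and BMP genes, 4 of 14 Hedgehog genes and 4 of 20 insulin and TOR genes. Transcription factor lists gave 3 of 7 TALE homeobox genes (achi, vis and exd), 1 of 11 Hox complex genes (bcd), 9 of 37 imaginal patterning genes and 3 of 22 neural precursor genes. Proteasome genes had 11 of 48, heat shock genes 6 of 18, circadian genes 3 of 10 and ecdysone synthesis genes 2 of 9. Of tissue markers, 4 of 9 glial, 5 of 16 fat body, 6 of 24 immune, 3 of 15 haemocyte, 2 of 11 germline, 3 of 23 testis differentiation, 0 of 11 meiotic arrest and 0 of 15 gut genes were bound.

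The tagged gene had a strong peak at its own promoter. The achi peak (2R 12514369 to 12515225, dm6, promoter) had its summit at 12514705, 307 bp from the nearest TSS of achi (FBgn0033749, 2R 12511534 to 12515062, minus strand), and ranked 24 in the optimal list. It ranked 30, 15 and 28 in replicates 1, 2 and 3, and a further summit at 12514957 ranked 989. The neighbouring vis (FBgn0033748, 2R 12507896 to 12510615, minus strand) had a promoter peak with its summit at 12510809 and rank 1706, and an intron of fdl held a peak with its summit at 12506645 and rank 2312. No TGACAG lay within 100 bp of the achi or vis promoter summits. Because achi and vis are near-identical, reads may be shared between them. The labels speak both of a transgenic line and of an insertion targeting achi, and do not settle whether the flies carried an extra copy of the region.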

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

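The nearest gene and promoter peaks only settings, and the alternatives for genomic classes, other fixed words and named genes, were chosen after seeing the data. The promoter share and the lower frequency of TGACAG in distal than in promoter peaks kept their direction and side of the threshold in the alternatives run for each. The count of lists called, 12, lay between 8 and 16, and 7 to 11 of the 12 calls were kept. The share of peaks recovered in all replicates lay between 38.1% and 96.5%, lowest with shorter replicate lists and highest in the stronger 50% of peaks. Why the results named next moved was not tested, except where the setting itself shows it. Agreement between replicates ranged from 0.840 to 0.864 when a replicate was left out, was 0.820 with the summit inside the replicate's region and 0.469 on the saturated -log10 q. The odds ratio of the X was 1.02 with a 200 bp window and 0.971 among the stronger 50% of peaks. The ratio of TGACAG at summits ranged from 1.13 to 1.199 without 1 replicate and was 1.09 with a 200 bp window, 1.15 for TTGACAG and 0.779 in distal peaks only. Its rank among hexamers was 344 in the stronger 50% of peaks, 393 with a 50 bp window and 8 in promoter peaks only. The rank difference of peaks with TGACAG was 10.2 with a 50 bp window, 2.62 with a 200 bp window and 0 on -log10 q, where most peaks are tied. With summits in the gene body 11 lists were higher. The count of lower lists was 3 without any 1 replicate, in the stronger 50%, with a 200 bp window and by nearest gene.

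Odds ratios of lists that were not called crossed 1 as follows, none of them called there. Without 1 replicate, ecdysone synthesis ranged from 1.15 to 1.21, insulin and TOR from 0.711 to 1.02, immune genes from 0.806 to 1.12 and imaginal patterning from 0.780 to 0.820. In the stronger 50% of peaks the values were 1.61 for ecdysone synthesis, 1.25 for germline, 0.434 for TGF-beta and BMP, 0.434 for Hedgehog, 0.806 for immune and 0.156 for imaginal patterning genes. With a 200 bp window they were 1.42 for proteasome, 0.673 for glia, 0.359 for fat body and 0.489 for immune genes, and with 1000 bp 1.01 for germline and 1.15 for insulin and TOR. In the gene body they were 2.96 for Hox, 1.33 for insulin and TOR, 1.41 for neural precursor and 1.64 for muscle genes. By nearest gene they were 1.27 for ecdysone synthesis, 0.626 for mitochondrial ribosomal and 0.892 for immune genes. The palindrome TGACANNTGTCA gave no ratio in the stronger 50% of peaks, where no flank held it. Depth is unknown, so which missing peaks reflect depth cannot be read from these lists.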

Other observations

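The gene groups, noncoding classes and gene body counts in the next 2 paragraphs were chosen after seeing the data, as were the tests of active promoters and the restriction to genes with 1 TSS, of base composition at promoters and for CACTGA, of ribosomal protein genes alone, of the anagrams and both tests at achi.

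Of 17 genes of the signal recognition particle and the translocon, 13 were bound (76.5%), among them Sec61alpha, Sec61beta, Sec61gamma, Srp14, Srp54k, Srp68 and Tapdelta. The group was picked after Sec61gamma was seen among the leading peaks, so no p-value is given for it or for the groups beside it: translation factors (18 of 53), aminoacyl-tRNA synthetases (8 of 18), the V-ATPase (12 of 33), vesicle coat proteins (5 of 11) and small nuclear ribonucleoproteins (1 of 8). A summit lay within 500 bp of a TSS in 24 of 290 tRNA genes, 16 of 269 snoRNA genes, 1 of 32 snRNA genes and 375 of 3261 ncRNA genes (11.5%, Wilson 95% interval 10.4% to 12.6%).

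By raw count, not adjusted for gene length, the most distal summits lay in the body of the cell adhesion gene kirre (X, 2740384 to 3134532, 394 kb), with 33, then sbb with 29 and Snoo with 26. The homeobox gene hth, a TALE-class partner of Hox proteins, held 19, as did the Wnt receptor gene fz, and Mnt held 17 in 29.9 kb. Longer genes offer more room for summits, and no excess over length was tested.

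TGACAG was frequent at the strongest promoter peaks, found at 38.2% of those among the 250 strongest peaks. Capture of active promoters without regard to sequence, base composition or ribosomal protein genes alone could account for this frequency. The first stays open. Among genes with 1 TSS, promoters with TGACAG within 200 bp were bound in 20.2% of 1429 genes and others in 16.4% of 8817 (odds ratio 1.29, 95% interval 1.11 to 1.48; 1.73 over all genes, where more TSSs give more chances both to hold a word and to be bound), but active promoters that share the word would show the same. The promoters of 7 of its 179 anagrams were bound more often. These include ACAGTG and CGATAG, leading hexamers of these same peaks, so the anagrams are not neutral controls. The values argue against the second as far as GC content goes. Among the 250 strongest peaks, promoter peaks with a GC match held TGACAG in 39.3% of cases. Low-ranked promoter regions of the same GC content held it in 6.87% (ratio 5.72, 95% bootstrap interval 4.19 to 8.07). Matching hardly moved the share in those regions (6.87% against 6.60%), so differences in GC content account for little of the excess. Composition beyond GC content was not tested. Against the last, without ribosomal protein genes 34.2% of the strongest promoter peaks held it, against 10.04% of weaker ones. Promoters with TGACAG were bound more often than those of 98.9% of its anagrams, with ACAGTG (34.3%) and CCGTTA (32.04%) higher, and of 96.1% in genes with 1 TSS, where ACAGTG (23.5%), CGATAG (23.2%), GCTAGA, AGCTAG, GCGATA, CCGTTA and GTGACA were higher. Since its enrichment at promoter summits was already known, this does not test recognition of TGACAG by the tagged protein. That hypothesis remains open beside other factors that share the word. Within ribosomal protein genes 18 of 23 with TGACAG and 49 of 69 without it were bound (odds ratio 1.46, 95% interval 0.441 to 5.74). This interval holds both 1 and the 1.73 over all genes, so the comparison bears on the hypothesis in neither direction.

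Distal peaks held TGACAG in 5.95% of summit windows against 7.64% of flanks, and CACTGA, a word picked from the leading distal hexamers, in 17.96% against 8.90%. AT-rich sequence could produce the former, and it cannot be told apart from other explanations, since the ratio to low-ranked distal regions of the same GC content was 0.912 with an interval that includes 1 (95% bootstrap interval 0.793 to 1.05). For CACTGA the ratio was 1.68 (95% bootstrap interval 1.53 to 1.85). Matching hardly moved its share in the low-ranked regions (10.7% against 10.5%), while the same matching lowered that of TGACAG there. These values argue against GC content as the source of the excess of CACTGA over low-ranked regions. Composition beyond GC content was not tested for CACTGA. Annotated transposable elements held 0% of the 1090 distal summits with CACTGA (Wilson upper bound 0.351%), but they held only 0.280% of all distal summits and make up 5.93% of the genome, so reads from repeats may have been lost in mapping, which was not tested. The word was not limited to weak peaks either, with 22.4% of the 500 strongest distal peaks against 17.6% of the rest. What stays open is whether the tagged protein, another factor at open sites or the shared control places peaks there; none of these was tested, and the design, with 1 group, gives no biological contrast.

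The peak at achi, at rank 24, may reflect extra copies of the region, if the tagged gene is an added copy and not an edited one, which the labels do not settle. Within 20 kb of achi, 6 of 12 pooled regions passed the authors' threshold (50%, exact 95% interval 21.1% to 78.9%), against 30.5% on 2R (exact binomial p = 0.206). These regions include the achi promoter summits at 12514705 and 12514957, which passed and belong to the peak to be explained. With 12 regions, extra copies cannot be told apart from their absence. Of the achi promoter summits, 0 had TGACAG within 100 bp, so binding through that exact word close to the summit has little in its favour. This absence was already known, and it says nothing of variants of the word or of sites further away. Reads shared with vis were not tested.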
